A study of Mus musculus with 5 samples.

How the data were processed

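Gene expression was measured by droplet sequencing with the 10x Genomics Chromium 3′ chemistry in tibialis anterior muscle, a hind-limb muscle made mostly of fast fibres, of female C57BL/6 mice aged 26 months. Frailty had been scored with an index of accumulated deficits; animals at or above an index of 0.18 form the frail group and those under it the controls, per the labels. There were 5 libraries, 2 frail and 3 control, and the series text describes them as coming from separate mice. The labels describe the preparation in 2 ways. The series text describes enzymatic digestion and a suspension of whole cells, and the sample protocol describes lysis and sorting of nuclei. The sources used here do not settle which was used, and the barcodes are called cells below. The median share of mitochondrial UMIs among retained cells was 3.09% to 4.17% per library. The tests had been laid out for nuclei before the data were examined, and they were run unchanged.

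The deposited matrices hold UMI counts per gene and barcode, made with Cell Ranger 7.0.0 per the file headers. The submitters' processing notes also list Seurat 4.1.2 and the build GRCm38. The gene annotation, the barcode filter and the steps for which these tools were used are not given in the sources used here. The deposited matrices hold 56922 barcodes and 55357 genes, and the lowest total of a barcode is 500 UMIs in each library. Total UMIs were 72043464 and 70155746 in frail 1 and 2, and 68170531, 71140868 and 90942121 in control 1 to 3. Gene positions come from GENCODE vM21 on GRCm38, in which 52081 of the 55357 gene identifiers (94.1%) were matched.

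Barcodes with at least 200 detected genes and at most 10% mitochondrial UMIs were kept. Scrublet scores were computed per library, and the highest-scoring barcodes were removed at a rate of 0.4% per 1000 barcodes. This left 48060 cells, 77.9% of the barcodes of frail 1 and 84.9% to 87.9% of the other libraries. The share of barcodes above 10% mitochondrial UMIs was 17.2% in frail 1 and 7.49% to 11.2% elsewhere. Counts were log-normalised, 2000 genes variable within libraries and 30 principal components were used with 15 neighbours and no integration across libraries, and Leiden clustering at resolution 1 gave 37 clusters. Clusters were named from marker lists of 20 cell types fixed before the data were examined. A cluster needed at least 3 raised markers. It stayed unnamed where at least 3 markers of another list were raised too and that list was raised at least 0.6 times as strongly. It also stayed unnamed where its top 10 genes held more markers of another list than of its own. The same held where its cells were shallow with no marker of the list among the top 10 genes. This scoring was set after the data were seen. It left 7 clusters unnamed, which held 4.09% and 3.88% of the cells of frail 1 and 2 and 6.26%, 7.74% and 12.6% of those of control 1 to 3. The 30 named clusters formed 15 classes, each called by its type followed by "like". The name myonuclei-like marks cells or fragments led by myofibre transcripts.

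UMI counts were summed per library over all retained cells and over 6 classes, so that the library is the replicate. Sums were tested with edgeR 4.0.16 (quasi-likelihood F test, robust estimation, TMM factors, filterByExpr with the group) and Benjamini-Hochberg adjustment at 0.05. CPM of tested genes is scaled by the TMM factors. Values called plain CPM are UMIs of a gene over all UMIs of the same sum, with no such factor. Log2 fold changes are frail over control, with standard errors from the fit. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, and again with a correlation estimated from the residuals and not allowed below 0. There were 26 lists, fixed before the data were examined, and those with at least 4 measured members were tested, 24 of them in all cells. Class shares were tested with edgeR on cell numbers with the library's retained cells as offset, beside an exact two-sided permutation test over the 10 ways of choosing 2 of the 5 libraries, whose smallest possible p is 0.1. The frail effect in myonuclei-like cells was compared with that in fibro-adipogenic-like cells by limma-trend on the difference of log2 CPM between the classes within each library. Intervals on shares are 95% Wilson intervals, and limits on counts of 0 rest on 3 counts; both cover counting error only. The software was R 4.3.3, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0 and scipy 1.17.1.

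Genes are named by a rule fixed before the data were examined. For all cells and for myonuclei-like cells it takes the 10 largest rises and 10 largest falls among genes past the adjusted threshold, with average log2 CPM of at least 3, every frail library on one side of every control library and a symbol that is not a clone or predicted name. For the other classes it takes 4 and 4. In any set of cells where none pass, it takes the 5 with the smallest p. It adds Gdf15, Gfral, Ret, the adult myosin heavy chains, Trim63, Fbxo32, Mstn, Cdkn1a, Cdkn2a, Col1a1, Col3a1 and Pax7 in any fit that keeps them, and from each described list the 4 members with the smallest p. Other genes are said to have been chosen after their values were seen.

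The count tests were tested on simulated sums of 5 libraries in which 200 genes were changed by a log2 fold of 1 or 2. edgeR recovered 15.5% and 67.3% of those it tested in all cells, 1.10% and 13.2% in myonuclei-like, 33.0% and 82.5% in fibro-adipogenic-like, 36.5% and 87.6% in endothelial-like, 38.8% and 91.5% in mural-like, 31.6% and 89.6% in macrophage-like and 20.0% and 83.3% in satellite-like cells. It made 17, 1, 13, 8, 17, 17 and 9 false calls in the same order. DESeq2 recovered 37.0% and 80.0% in all cells, with 76 false calls. In myonuclei-like cells it recovered 0% at either fold, with 1 false call. On simulated sums of all cells, camera called the 1 shifted list and 0 of 20 unshifted lists. The simulated genes were drawn independently of each other. False calls that arise where the genes of a list vary together could therefore not show there. The test of a difference of effects was tried on simulated fibro-adipogenic-like and endothelial-like sums, not on the shallow myonuclei-like sums it was used on. There it recovered 64.3% of genes changed by a log2 fold of 2, with 6 false calls.

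Alternatives fixed beforehand were DESeq2, library totals or upper-quartile factors in place of TMM, no low-count filter, the replicate number as a block, doublets kept, at most 5% mitochondrial UMIs, at least 500 detected genes, all deposited barcodes, sums thinned to the shallowest library, Leiden resolutions of 0.5 and 2, other prior counts, and each library left out in turn. A limit of 20% mitochondrial UMIs, edgeR without robust estimation and removal of a keratin-led cluster were added after the data were seen. A comparison of mouse substrains that had been considered was not analysed here.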

Results

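Tibialis anterior muscle of aged female mice was compared between 2 frail animals and 3 controls, with 1 droplet library of UMI counts per animal. The series title names GDF15, a circulating stress cytokine, its receptor GFRAL and the risk of sarcopenia, the loss of muscle with age. The frail libraries held 72043464 and 70155746 UMIs in 11401 and 11690 barcodes, and the control libraries 68170531, 71140868 and 90942121 in 9791, 10737 and 13303 barcodes. After filtering, 8879 and 10000 frail cells and 8310, 9440 and 11431 control cells remained, with a median of 6115, 5175, 6839.5, 5979 and 6530 UMIs per cell. Values below are listed in this order, frail 1 and 2, then control 1 to 3. Frail 1 lost the largest share of barcodes to the mitochondrial limit (17.2%, against 7.49% to 11.2% in the others). Libraries are the replicates throughout, so every comparison rests on 2 against 3, and an exact test cannot give a p under 0.1.

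Gdf15 (ENSMUSG00000038508, chromosome 8, 70629393 to 70632456 in GRCm38) was higher in both frail libraries than in any control library. Over all retained cells it stood at 28.0 and 20.7 plain CPM in frail muscle (24.3 ± 5.15, SD, n = 2) and at 13.4, 14.3 and 16.1 in controls (14.6 ± 1.39, SD, n = 3). The fitted change was 1.65-fold (log2 0.72, SE 0.19), which did not pass over all genes (edgeR adjusted p = 0.589; DESeq2 adjusted p = 0.104). Of the 2 measured genes of the ligand and receptor list, Gdf15 passed and Ret did not when adjusted over the list alone (edgeR adjusted p = 0.0148 for Gdf15). Without frail 1 the log2 change was 0.44 (edgeR adjusted p = 0.705).

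In macrophage-like cells Gdf15 stood at 176 and 210 plain CPM in frail libraries, above every other class, and at 47.1, 44.0 and 156 in controls, where mural-like cells stood above them in control 1 and 2. The fitted log2 change there was 1.26 (edgeR adjusted p = 1.00). It was 2.05 without control 3 and passed there (edgeR adjusted p = 0.00740). In fibro-adipogenic-like cells, the matrix-producing stromal cells of muscle, Gdf15 stood at 5.15 and 4.21 against 1.69, 1.44 and 3.38 (log2 1.09; edgeR adjusted p = 0.683 over all genes and 0.0314 adjusted over the list alone). In endothelial-like cells it stood at 27.6 and 12.2 against 6.50, 12.2 and 10.1 (log2 1.07; edgeR adjusted p = 1.00). The log2 change in endothelial-like cells was 0.28 without frail 1 and 1.59 without frail 2, and Gdf15 passed there only with no low-count filter (edgeR adjusted p = 0.00991). In satellite-like cells it stood at 16.9 and 20.8 against 9.47, 8.04 and 18.5. Mural-like cells, the pericytes and smooth muscle of vessels, had 69.8 and 48.1 against 55.4, 59.5 and 58.0 (log2 0.09). Macrophage-like cells held 19.8% and 43.2% of all Gdf15 UMIs in frail libraries and 28.0%, 18.1% and 38.2% in controls, and mural-like cells 33.7% and 18.3% in frail libraries and 40.2%, 33.9% and 21.1% in controls. Lymphatic-endothelial-like cells reached 312 and 294 plain CPM in control 2 and 3, on 56 and 40 UMIs.

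**Figure D1:**
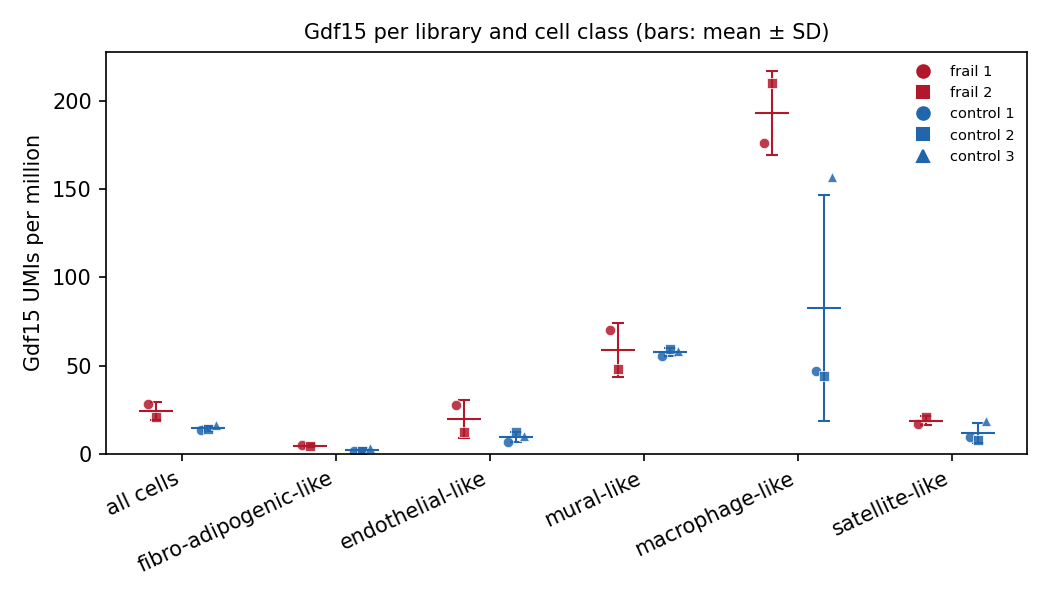
Gdf15 in plain CPM (vertical axis) in all retained cells and in 5 cell classes, with points for libraries and bars for mean ± SD over 2 frail (red) and 3 control (blue) libraries. In macrophage-like cells the frail libraries stand at 176 and 210 and control 3 at 156, apart from the other controls.

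Gfral (ENSMUSG00000059383, chromosome 9, 76164102 to 76213657), the receptor of GDF15 known from the hindbrain, had 0 UMIs in each of the 5 libraries. With all deposited barcodes counted, this allows up to 0.0416 and 0.0428 plain CPM in frail and 0.0440, 0.0422 and 0.0330 in control libraries. Ret (chromosome 6, 118151745 to 118197718), the co-receptor of GFRAL, was present at 15.8 and 4.19 against 12.7, 6.38 and 18.4 plain CPM (log2 −0.30, SE 0.66; edgeR adjusted p = 0.981). Fibro-adipogenic-like cells held 72.5% to 85.0% of the Ret UMIs of each library.

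Over all retained cells, the genes with the smallest p were the lipase Daglb, which makes the endocannabinoid 2-arachidonoylglycerol, the cytokine Il6, the Wnt antagonist Sfrp5, Cib2 and Gkn3. Daglb stood at 18.1 and 19.4 CPM in frail and 53.5, 51.3 and 52.8 in control libraries (log2 −1.49, SE 0.14), and Il6 at 26.2 and 25.7 against 65.6, 67.3 and 65.8 (log2 −1.35, SE 0.13). Cib2 was lower in frail libraries (log2 −1.75, SE 0.18), at 6.33 and 5.97 against 17.6, 21.8 and 22.4. Sfrp5 was higher (log2 1.26, SE 0.13). It led the perineurial-like cluster, where it stood at 2231 and 2741 plain CPM in frail and 1996, 1776 and 1983 in control libraries, and it was also found in Schwann-like cells. Gkn3 was also higher (log2 2.04, SE 0.22), and it was among the leading genes of an arterial endothelial cluster.

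None of these genes passed. edgeR called 0 of 19772 genes, with a smallest adjusted p of 0.181, against 1110 at an unadjusted p under 0.05 (988.6 by chance), of which 405 were higher and 705 lower. DESeq2 called 55 higher and 274 lower, Daglb, Il6, Cib2, Sfrp5 and Gkn3 among them. The frail libraries lay apart from all controls for 20.4% of genes, where chance gives 20%.

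Among the genes fixed beforehand, the fast myosin heavy chains were far lower in frail libraries, with log2 changes of −4.57 for Myh1, −4.14 for Myh2 and −5.32 for Myh4. Trim63, a ubiquitin ligase of muscle wasting, had a log2 change of −3.63 and Mstn, the growth inhibitor myostatin, −0.94. Fbxo32, another wasting ligase, stood at −0.18, the cell cycle inhibitors Cdkn1a and Cdkn2a at −0.21 and −0.57, the collagens Col1a1 and Col3a1 at −0.10 and 0.01, and the satellite cell factor Pax7 at 0.66. edgeR called none of the 11 in all cells, where the smallest adjusted p among them was 0.530, for Myh1. The sign turned without frail 2 for Cdkn1a (0.00), Cdkn2a (0.02) and Col1a1 (0.11).

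camera called 9 of 24 lists in all cells, all of them lower, and 0 with an estimated correlation. The lists of the TCA cycle (camera adjusted p = 0.106), of fatty acid oxidation and PPAR (0.670) and of insulin, IGF and mTOR (0.427) were not called. All 13 fast fibre genes were lower, with a median log2 change of −4.24 (camera adjusted p = 1.66e-18; adjusted p = 0.563 with an estimated correlation). All 13 were called lower when adjusted over the list alone, and 0 over all genes. They include the calcium store protein Casq1 (−3.57), the troponins Tnnt3 (−4.28) and Tnnc2 (−4.24) and the kinase Mylk2 (−2.79). Of 11 slow fibre genes 10 were lower (median −2.51; camera adjusted p = 7.61e-08; adjusted p = 0.450 with an estimated correlation), 6 of them adjusted over the list alone, such as Myl2 (−3.67) and the calcium pump inhibitor Sln (−5.75). Of 17 calcium handling genes, among which are also Casq1 and Sln, 15 were lower (median −1.76; camera adjusted p = 1.47e-10; adjusted p = 0.450 with an estimated correlation) and 10 passed adjusted over the list alone, for example Jsrp1 (−2.53) and Jph1 (−1.76).

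Among 19 glycolysis and glycogen genes 18 were lower (median −0.42; camera adjusted p = 1.22e-09; adjusted p = 0.563 with an estimated correlation), and 5 passed adjusted over the list alone. The largest changes were those of muscle isoforms, Pgam2 (−3.58) and Eno3 (−3.21). Of 42 oxidative phosphorylation genes 41 were lower (median −0.23; camera adjusted p = 4.98e-07; adjusted p = 0.746 with an estimated correlation), and the muscle isoforms Cox8b (−3.63), Cox7a1 (−2.52) and Cox6a2 (−4.35) stood far below the median. Ribosomal protein genes, a sign of RNA quality, had a median of −0.18 with 22 of 23 lower (camera adjusted p = 0.000104; adjusted p = 0.746 with an estimated correlation), and heat shock genes −0.20 with 20 of 21 lower (camera adjusted p = 0.00145; adjusted p = 0.644 with an estimated correlation), with Hspb8 at −1.07. Of 25 senescence and secretory genes 18 were lower (median −0.34; camera adjusted p = 0.0329; adjusted p = 0.644 with an estimated correlation), and only Il6 passed adjusted over the list alone. All 7 genes of MHC class II antigen presentation were lower (median −0.42; camera adjusted p = 0.0383; adjusted p = 0.746 with an estimated correlation), 0 of them adjusted over the list alone. Beside these, myonuclei-like cells made up 0.135% and 0.860% of frail and 4.22%, 8.42% and 2.97% of control libraries.

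**Figure D2:**
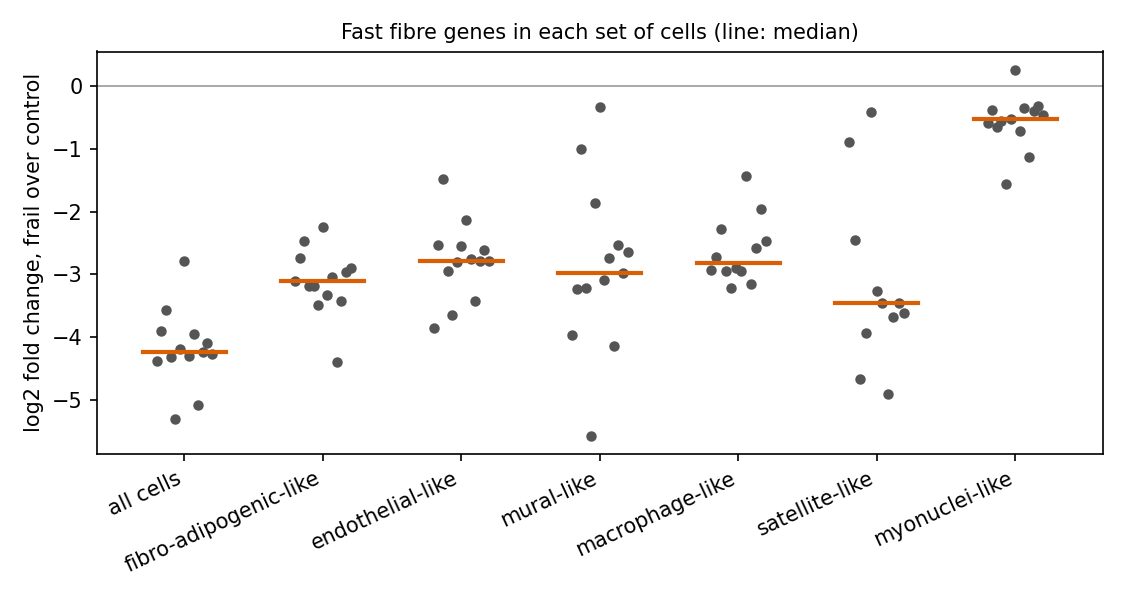
Log2 fold change of each fast fibre gene, frail over control (vertical axis), in all cells and in 6 cell classes, with a line at the median. The medians lie at −4.24 in all cells, between −2.78 and −3.46 in 5 classes and at −0.53 in myonuclei-like cells.

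The myonuclei-like share was 10.4-fold lower in frail libraries, but it did not pass (edgeR adjusted p = 0.112; exact permutation p = 0.2). edgeR called 0 of 15 classes, with 1 at an unadjusted p under 0.05, and the exact permutation test, whose smallest p is 0.1, cannot pass. The myonuclei-like share passed without control 1 (edgeR adjusted p = 0.00470), at Leiden resolution 2 (0.00300) and with the replicate number as a block (0.00196). The block fit leaves control 3, the only library with its number, out of the frail effect, and no label pairs the animals. The log2 change of the share was −2.60 without frail 1 and −5.25 without frail 2. Without control 3 only the cycling class passed (edgeR adjusted p = 0.0451, higher in frail). Schwann-like cells made up 4.43% and 2.70% of frail and 1.26%, 2.24% and 2.19% of control libraries (exact permutation p = 0.1), and perineurial-like cells, which sheathe nerves, 1.30% and 0.670% against 0.481%, 0.519% and 0.394% (exact permutation p = 0.1). Macrophage-like cells stood at 2.51% and 3.28% against 6.52%, 4.66% and 3.86% (exact permutation p = 0.2). Endothelial-like cells ranged from 30.4% to 43.3% in frail and from 17.1% to 33.6% in control libraries, and fibro-adipogenic-like cells from 29.4% to 33.3% and from 30.1% to 39.5%. Clusters left unnamed held 4.09% and 3.88% of frail and 6.26%, 7.74% and 12.6% of control libraries.

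**Figure D3:**
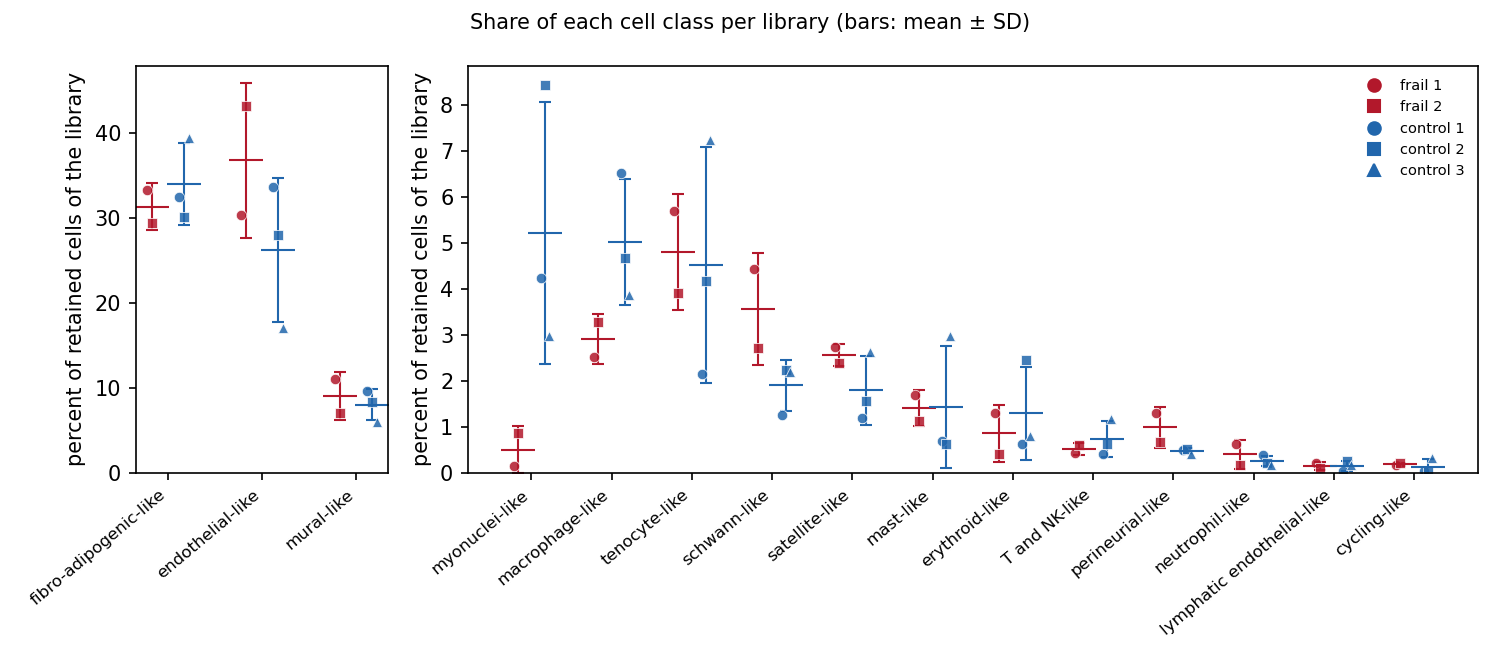
Share of each named class in percent of the retained cells of its library (vertical axes, separate scales for the 3 largest classes and the others), with points for libraries and bars for mean ± SD over 2 frail (red) and 3 control (blue) libraries. Myonuclei-like cells reach at most 0.860% of a frail library and at least 2.97% of a control library.

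In fibro-adipogenic-like cells 3 of 16106 genes passed. Aldh1l1 (ENSMUSG00000030088, chromosome 6, 90486427 to 90600203), a folate enzyme that oxidises 10-formyltetrahydrofolate, rose 8.37-fold (log2 3.07, SE 0.22; edgeR adjusted p = 0.00290), from 1.94, 2.90 and 2.76 CPM in controls to 22.1 and 20.4 in frail libraries. Dmkn (chromosome 7, 30763756 to 30781063), a secreted epithelial protein, fell (log2 −2.47, SE 0.24; edgeR adjusted p = 0.0172) to 11.0 and 7.29 CPM from 59.2, 51.6 and 41.8. In control 3, which alone held a keratin-led cluster of 971 cells, Dmkn also stood at 26.1 plain CPM in endothelial-like cells, against 1.35 and 1.95 in the other controls. Daglb (chromosome 5, 143464584 to 143505942) fell to 29.4 and 24.3 CPM from 96.9, 105 and 87.1 (log2 −1.85, SE 0.18; edgeR adjusted p = 0.0172). Daglb, like the inflammatory gene Ptx3, is also among the 10 leading genes of a cluster of 30 of these cells found only in control 2. In macrophage-like cells Daglb stood at 58.4 and 93.1 plain CPM against 79.2, 74.7 and 63.4. The inflammatory genes Il6 (log2 −1.39; edgeR adjusted p = 0.0850), Ptgs2 (−1.37; 0.244), Ptx3 (−1.75; 0.235) and Cxcl1 (−0.58; 0.716), named after their values were seen in the case of Ptgs2 and Ptx3, were lower in both frail libraries than in any control and did not pass.

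Aldh1l1 did not pass without frail 2 (edgeR adjusted p = 0.0805) or control 3 (0.0830), with log2 changes of 3.13 and 3.14. Dmkn and Daglb did not pass without frail 2 (edgeR adjusted p = 0.206), control 1 (0.0697) or control 3 (0.0830), nor at Leiden resolution 2 (0.945 and 0.997). In the same order the log2 changes were −2.20, −2.34, −2.59 and −3.85 for Dmkn and −1.71, −1.84, −1.91 and −1.28 for Daglb. The count of genes passing was 8 without frail 1, 0 without frail 2, 1 without control 1, 12 without control 2 and 0 without control 3. DESeq2 called 19 higher and 126 lower, 145 in all, and among the other splits of the 5 libraries it called 188 for frail 1 with control 3 and 134 for control 1 with control 2, where edgeR called 0.

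**Figure D4:**
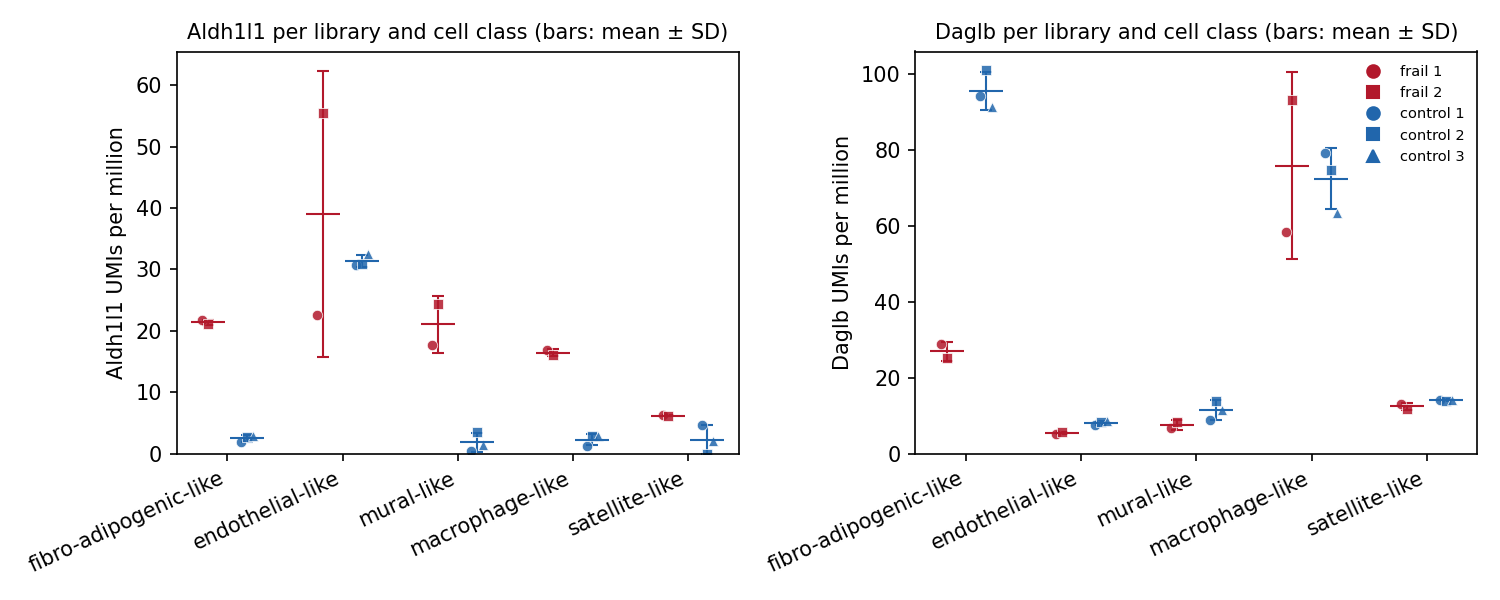
Aldh1l1 (left) and Daglb (right) in plain CPM (vertical axes) in 5 cell classes, with points for libraries and bars for mean ± SD over 2 frail (red) and 3 control (blue) libraries. In fibro-adipogenic-like cells Aldh1l1 stands at 21.7 and 21.2 in frail and at 1.88, 2.79 and 2.89 in control libraries.

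camera called 1 list higher and 8 lower of 24 in these cells, and 0 with an estimated correlation. As a group, MHC class II genes were lower in frail fibro-adipogenic-like cells, 7 of 7 with a median log2 change of −0.86 (camera adjusted p = 1.42e-08; adjusted p = 0.464 with an estimated correlation), and 5 passed adjusted over the list alone, among them H2-Ab1 (−0.95) and the invariant chain Cd74 (−0.86). Macrophage-like cells made up a smaller share of both frail libraries than of any control, and within them all 7 were higher (median 0.30; camera adjusted p = 0.212). Ribosomal protein genes, a sign of RNA quality, were called lower as well, 23 of 23 with a median of −0.18 (camera adjusted p = 0.00728; adjusted p = 0.816 with an estimated correlation). Of 17 circadian clock genes 15 were higher (median 0.26; camera adjusted p = 0.00435; adjusted p = 0.596 with an estimated correlation), 0 of them adjusted over the list alone, with Per3 at 0.76 and Tef at 0.38. The 13 fast fibre genes, which stromal cells are not known to express, had a median of −3.10 here (camera adjusted p = 4.66e-19; adjusted p = 0.464 with an estimated correlation).

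In endothelial-like cells the smallest p values belonged to the receptor Mrgprg (log2 −3.24), the muscle genes Pgam2 (−2.79), Mb (−2.31) and Xirp2 (−2.76), and the pentraxin Ptx3 (−2.30), all lower in both frail libraries. Of these Pgam2, Mb and Xirp2 are myofibre transcripts. Mrgprg and Ptx3 are among the 10 leading genes of a fibro-adipogenic-like cluster of 30 cells found only in control 2. edgeR called 0 of 14572 genes (smallest adjusted p = 0.508), with 574 at an unadjusted p under 0.05 (728.6 by chance), and DESeq2 called 4 higher and 45 lower. edgeR called 1 without frail 1 and 5 without control 2. Aldh1l1, chosen here after its values were seen, stood at 23.7 and 53.3 CPM against 31.2, 32.3 and 30.9 (log2 0.29, SE 0.30). The class was made up unequally: a cluster led by Aqp1, Iigp1 and Timp4 held 51.4% of it in frail 1 and 5.87% in frail 2. camera called 9 of 24 lists, all lower, and 0 with an estimated correlation. Fast fibre genes had a median of −2.78 (camera adjusted p = 1.38e-25; adjusted p = 0.336 with an estimated correlation) and immediate early genes −0.22 with 17 of 19 lower (camera adjusted p = 0.000848; adjusted p = 0.489 with an estimated correlation), Egr1 at −0.76 and Fosb at −0.62, 0 of them adjusted over the list alone.

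The genes with the smallest p in mural-like cells were Ccl2, Cxcl10, Ccl6, F13a1 and C1qb, all lower in both frail libraries, and none passed. Ccl2, which attracts monocytes, stood at 21.1 and 15.2 CPM against 100.4, 80.7 and 59.3 (log2 −2.13, SE 0.27; edgeR adjusted p = 0.0584), and the interferon-induced Cxcl10 at 18.0 and 9.38 against 123, 113 and 70.8 (log2 −2.88, SE 0.34; edgeR adjusted p = 0.0584). Ccl6 (−1.95), F13a1 (−2.93) and the complement gene C1qb (−1.78), all abundant in macrophages, were lower too, and Aldh1l1, chosen here after its values were seen, was higher (log2 3.54; edgeR adjusted p = 0.0656). edgeR called 0 of 12538 genes, with 451 at an unadjusted p under 0.05 (626.9 by chance), and DESeq2 called 1 higher and 50 lower. edgeR called 6 without control 1, 18 without control 2 and 15 without control 3. camera called 8 of 24 lists, all lower, and 0 with an estimated correlation. All 6 measured MHC class II genes were lower (median −0.78; camera adjusted p = 9.12e-08; adjusted p = 0.367 with an estimated correlation), 4 of them adjusted over the list alone. All 19 immediate early genes were lower (median −0.40; camera adjusted p = 3.27e-06; adjusted p = 0.599 with an estimated correlation), with Egr1 (−1.11) alone passing adjusted over the list alone. Of 22 senescence and secretory genes 13 were lower (median −0.18; camera adjusted p = 0.0151; adjusted p = 0.430 with an estimated correlation), and Ccl2, Il6 (−2.13), Cxcl1 (−1.42) and Ccl7 (−1.54) passed adjusted over the list alone. Fast fibre genes had a median of −2.98 (camera adjusted p = 9.85e-27; adjusted p = 0.367 with an estimated correlation).

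In macrophage-like cells Aldh1l1 was higher, at 18.2 and 15.1 CPM against 1.24, 3.00 and 2.72 (log2 2.86, SE 0.40; edgeR adjusted p = 0.0791). The muscle genes Pgam2 (−2.75), Atp2a1 (−2.73), Pvalb (−3.16) and Tnnc2 (−2.58) were lower, with edgeR adjusted p from 0.0791 to 0.0940. edgeR called 0 of 11646 genes, with 524 at an unadjusted p under 0.05 (582.3 by chance), and DESeq2 called 2 higher and 24 lower. edgeR called 10 without control 1, 13 without control 2 and 19 without control 3. camera called 1 list higher and 3 lower of 23, and 0 with an estimated correlation. The 12 measured fast fibre genes had a median of −2.82 (camera adjusted p = 7.08e-26; adjusted p = 0.336 with an estimated correlation). Of 19 immediate early genes 17 were higher (median 0.24; camera adjusted p = 0.0163; adjusted p = 0.794 with an estimated correlation), 0 of them adjusted over the list alone, with Jund at 0.50 and Klf2 at 0.50. The 5 blood carry-over genes, not called as a list, were all higher with a median of 2.36 (camera adjusted p = 0.248), and of 33 extracellular matrix genes 24 were lower (median −0.43; camera adjusted p = 0.416).

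In satellite-like cells, the muscle stem cells, 3 of 10097 genes fell and 0 rose. The chemokine Ccl2 (chromosome 11, 82035571 to 82037453) fell to 74.5 and 81.9 CPM from 387, 282 and 240 (log2 −1.94, SE 0.23; edgeR adjusted p = 0.00792). The syntaxin Stx11 (chromosome 10, 12938209 to 12964298), a membrane fusion protein, fell to 3.60 and 7.34 CPM from 31.3, 30.9 and 30.3 (log2 −2.46, SE 0.38; edgeR adjusted p = 0.0392). The other gene was the predicted transcript Gm43430 (log2 −2.14; edgeR adjusted p = 0.0177), named after its values were seen. Pax7 stood at 390.5 and 384.5 CPM against 347, 226 and 560 (log2 0.03). camera called 4 of 23 lists, all lower, and 0 with an estimated correlation. Of 31 interferon response genes 23 were lower (median −0.33; camera adjusted p = 8.42e-05; adjusted p = 0.745 with an estimated correlation), with Ifit1 (−1.23) alone passing adjusted over the list alone. Of 23 ribosomal protein genes 21 were lower (median −0.18; camera adjusted p = 0.0102; adjusted p = 0.773 with an estimated correlation). The 11 fast fibre genes had a median of −3.46 (camera adjusted p = 7.70e-16; adjusted p = 0.745 with an estimated correlation).

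No satellite gene passed without control 1, where the edgeR adjusted p of Ccl2 was 0.148, of Stx11 0.319 and of Gm43430 0.245. Stx11 and Gm43430 did not pass without control 3 either (edgeR adjusted p = 0.123 and 0.0749) or with thinned sums (0.146 and 0.0674), and Stx11 also not with library totals (0.0625) or without robust estimation (0.0661). The count was 31 without frail 1, 17 without frail 2 and 11 without control 2, and DESeq2 called 1 higher and 12 lower.

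The myonuclei-like sums rest on 12 and 86 frail cells, with 17491 and 196929 UMIs, against 1879774, 3172715 and 1289195 UMIs in controls. In them 5 slow fibre genes fell, Sln (log2 −3.44), Tnnt1 (−3.13), Tnni1 (−2.91), Myl2 (−2.31) and Tnnc1 (−2.17). The stromal genes Igfbp5 (−3.75) and Dcn (−2.06) and the glycogen-targeting subunit Ppp1r3c (−2.40) fell too, each of these genes with an edgeR adjusted p under 0.05. These calls depend on the scaling, since with library totals in place of TMM only 1 gene was called lower in these sums. The slow fibre list was not called there (10 of 10 lower, median −2.24; camera adjusted p = 0.0885). Tnnt1, Tnni1, Myl2 and Tnnc1 had 0 UMIs in frail 1, and without it their log2 changes were −2.84, −2.71, −2.03 and −1.87, while Myl2 stood at −1.20 and Tnnc1 at −1.57 without control 3. Sln stood at −4.98 without frail 1 and −1.48 without frail 2. Adamts5 fell to 0 UMIs in both frail libraries, at least 3.83-fold lower than the control mean when 3 counts over the group are taken as the floor. It averaged 53.6 plain CPM in control myonuclei-like cells and 930 in control fibro-adipogenic-like cells. It passed in 3 of 17 alternatives, and with doublets kept its log2 change was 0.45 (edgeR adjusted p = 0.882). Without frail 2 the log2 change of Ppp1r3c was −1.28, and without control 3 that of Dcn was −1.07, neither passing. Aldh1l1 rose (log2 4.20, SE 0.92; edgeR adjusted p = 0.00534) on 2 and 9 UMIs against 2, 15 and 1. The endothelial genes Cd93 (2.36), Cd300lg (2.16) and Fabp4 (2.06) rose with it, as did Gvin-ps7 (2.75) and Tmem140 (2.11). Without frail 2 Fabp4 stood at 0.26, Tmem140 at 0.40 and Cd300lg at 1.18, and with doublets kept Cd93 stood at 1.38 and Gvin-ps7 at 1.44, none of them passing. Fabp4 averaged 538 plain CPM in control myonuclei-like cells and 20452 in control endothelial-like cells. Every other gene called higher in myonuclei-like cells also averaged more in control endothelial-like cells. Aldh1l1 stood there at 31.4 against 2.19 plain CPM, Gvin-ps7 at 281 against 7.20 and Tmem140 at 284 against 41.8.

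edgeR called 15 genes higher and 9 lower of 7126, and 0 without frail 1 or without frail 2, where 1 frail library is left. The count was 1 with sums thinned to the shallowest library, 1 without robust estimation, 15 without control 1, 3 without control 2 and 49 without control 3. With library totals in place of TMM 16 were called higher and 1 lower, and with upper-quartile factors 35 and 15. DESeq2 called 0, but on simulated myonuclei-like sums it also recovered 0% of genes changed by a log2 fold of 1 or 2. Its 0 calls therefore cannot decide on the edgeR calls. Fast fibre genes had a median of −0.53 and were not called as a list (camera adjusted p = 0.673). Of 18 interferon response genes 13 were higher (median 0.59; camera adjusted p = 0.00219; adjusted p = 0.946 with an estimated correlation), with Parp14 (2.40) and Isg15 (1.91) passing adjusted over the list alone. Isg15 was at 0 UMIs in frail 1, so its higher level rests on frail 2. The mitochondrially encoded transcripts, a sign of RNA quality, were called higher as a list (median 0.14, 7 of 13 higher; camera adjusted p = 0.0472; adjusted p = 0.946 with an estimated correlation), 0 of them adjusted over the list alone. Both list calls ended without frail 1 and without frail 2. Only 1 list was called higher with doublets kept, with no low-count filter, with the replicate block, without control 1 and without control 3, and 1, 0, 2, 2 and 1 were called lower there. Without control 2 the calls were 2 higher and 2 lower. Neither Trim63 (0.57) nor Fbxo32 (1.05) passed.

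The fast myosin Myh4 made up 32.6% and 78.8% of adult myosin heavy chain UMIs in frail myonuclei-like cells and 78.7%, 67.6% and 60.4% in controls. The difference of means was −13.2 percentage points (exact two-sided permutation p = 0.7), and it was 9.95 without frail 1, which holds 46 such UMIs (95% Wilson interval of its share 20.9% to 47.0%). Myh1 stood at 67.4% and 20.2% against 20.7%, 29.6% and 33.2% (exact permutation p = 0.5) and Myh2 at 0 and 0.962% against 0.555%, 2.84% and 4.28% (exact permutation p = 0.3). The slow myosin Myh7 had 0 UMIs in both frail libraries, which allows for a share of up to 7.71% and 0.915% by the Wilson interval, and reached 2.08% in control 3 (exact permutation p = 0.5).

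No gene was called, at an adjusted threshold, as differing in frail effect between myonuclei-like and fibro-adipogenic-like cells. The recovery of this test was not tried on sums this shallow. limma-trend called 0 of 6963 genes (smallest adjusted p = 0.242), with 745 at an unadjusted p under 0.05, more than chance gives over independent genes. It called 646 without frail 1 and 6393 without frail 2, where the myonuclei-like side rests on 1 frail library that is assumed to vary like the controls.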

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

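All tests of explanations in this part were chosen after at least part of the result they bear on had been seen. Cells of 2 unnamed clusters stood out because each cluster lay almost entirely in 1 control library and belonged to no named class. They still counted in the sums over all cells and in the retained cells over which class shares were taken. The larger cluster held 8.49% of the retained cells of control 3. A keratin-led cluster (Defb6, Krt17, Lgals7) held 971 cells of control 3 and none of any other library, and a cluster led by Krt18, Ankrd2 and Ankrd1 held 104 cells of control 2 out of 111. No explanation was tested for either.

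Fast fibre transcripts were lower in frail libraries in all cells and in 5 classes other than myonuclei-like cells, with a median over these 6 sums of −3.04, and by −0.53 in myonuclei-like cells. Lower expression within the remaining frail myofibre fragments would need a fall there at least as large, but the gap was 2.51 on the log2 scale. The SD over the genes was 0.429, which measures no spread between libraries, and the frail sums rest on 12 and 86 cells. The class is named from such transcripts, so fragments with less of them could fall outside it. The test therefore cannot decide on lower expression in the frail muscle. Free RNA from myofibre fragments keeps its genes in 1 ratio in every class, and the log2 ratio of fibro-adipogenic-like to myonuclei-like CPM had an SD over the 13 genes of 0.291 to 0.493 in the control libraries. Free RNA is therefore a candidate source of the fast fibre change in the other classes. Why frail libraries hold fewer fragments stays open, since loss during preparation and a difference between the muscles were not told apart.

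Aldh1l1 was higher in frail fibro-adipogenic-like, mural-like and macrophage-like cells but not in endothelial-like cells, the class in which controls express it most. The first test of free RNA from 1 class did not decide, since of 7 classes only the highest, endothelial-like cells, lay within 2-fold of the highest and 0 lay 10-fold below it in both frail libraries. A test on endothelial markers, chosen after that outcome, argues against endothelial RNA: the ratio of fibro-adipogenic-like to endothelial-like CPM was 0.961 and 0.381 for Aldh1l1 in the frail libraries and at most 0.0216 for 7 endothelial markers, at least 17.6 times lower. A later test was made for 3 classes together and split by class after it did not decide. It set satellite-like Aldh1l1 UMIs per cell against those of each class. The upper 95% bound of the ratio was at most 0.617 times the lowest marker ratio for fibro-adipogenic-like cells. It was up to 2.40 times for mural-like and macrophage-like cells, where free RNA may contribute. The marker ratios carried no bound, though a marker had as few as 11 and 17 satellite-like UMIs in frail 1 and 2. The test therefore does not decide for fibro-adipogenic-like cells either. An inherited difference acting by an equal fold in every class is argued against by log2 changes from 0.29 to 3.54 over 4 class fits, a range of 3.24. The range cannot decide on an equal added amount, since control levels differed between classes. The control mean was 31.4 plain CPM in endothelial-like and 2.52 in fibro-adipogenic-like cells. A class-specific inherited difference and frailty itself stay open, untested.

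Of 5 inflammatory genes chosen after their values were seen, Il6, Cxcl1, Ptgs2 and Ptx3 were lower in both frail libraries than in any control in fibro-adipogenic-like cells and Ccl2 (log2 −0.43) was not, with a median log2 change of −1.37 over the 5, while the senescence and secretory list was not called there (camera adjusted p = 0.240). Handling stress would lower immediate early genes along with them, but their median there was −0.0802 (SD 0.221). Yet all 19 immediate early genes were lower in mural-like and 17 of 19 in endothelial-like cells, each called as a list (camera adjusted p = 3.27e-06 and 0.000848). With an estimated correlation neither was called (camera adjusted p = 0.599 and 0.489). Heat shock genes were called lower in fibro-adipogenic-like cells too, 17 of 21 with a median of −0.24 (camera adjusted p = 0.0166; adjusted p = 0.816 with an estimated correlation). The same list was called lower in endothelial-like and mural-like cells (camera adjusted p = 1.29e-05 and 0.0262), but not with an estimated correlation (0.489 and 0.599). The immediate early genes alone therefore do not decide on handling stress. Free RNA from fewer macrophages is argued against for Il6 and Cxcl1 in fibro-adipogenic-like cells, where control CPM was at least 2.68 times that in macrophage-like cells (at least 6.13 times for Il6). The same test did not decide for mural-like cells, where control CPM over that in macrophage-like cells was at least 1.59 for Il6 but fell to 0.538 for Cxcl1 in control 3, and the lower genes there include the macrophage genes C1qb, F13a1 and Ccl6, so both explanations stay open and free RNA may contribute. A difference between frail and control animals stays open as well.

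DESeq2 called 329 genes in all cells for the real grouping, and 3 of the 10 splits of the 5 libraries gave at least as many, the real one included. The highest other split, frail 1 with control 3, gave 795, and control 1 with control 2 gave 509, while edgeR called 0 in all 10. The splits are too few for a share under 0.05.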

How the results depend on the processing

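A limit of 20% mitochondrial UMIs, no robust estimation and removal of the keratin-led cluster were alternatives chosen after seeing the data. The cause of the changes below was not tested. Numbers of genes passing were, in the order all cells, myonuclei-like, fibro-adipogenic-like, endothelial-like, mural-like, macrophage-like and satellite-like, 0, 24, 3, 0, 0, 0 and 3. With DESeq2, which recovered 0 changed genes in simulated myonuclei-like sums, they were 329, 0, 145, 49, 51, 26 and 13. With no low-count filter they were 15, 8, 322, 136, 83, 90 and 67. With 1 replicate left out they ranged from 0 to 49 in myonuclei-like, 0 to 12 in fibro-adipogenic-like, 0 to 5 in endothelial-like, 0 to 18 in mural-like, 0 to 19 in macrophage-like and 0 to 31 in satellite-like cells. Myonuclei-like cells gave 50 with upper-quartile factors, 51 with at least 500 detected genes, 1 with thinned sums and 1 without robust estimation. Fibro-adipogenic-like cells gave 1 at resolution 2. Mural-like cells gave 3 with doublets kept, 1 at 5% and 5 at 20% mitochondrial UMIs, macrophage-like cells 8 at 5%, 8 at 20% and 11 with thinned sums, and satellite-like cells 1 with thinned sums. Lists called went from 9 to 0 in all cells and from 2 to 0 in myonuclei-like cells with an estimated correlation, and to 1 in the latter with no filter; with 1 replicate left out they ranged from 6 to 13 and from 0 to 4. Classes called went from 0 to 1 at resolution 2 and ranged from 0 to 1 with 1 replicate left out. The difference of effects ranged from 0 to 6393 genes, the Myh4 share difference from −36.3 to 9.95 and the log2 change of Gdf15 from 0.44 to 0.97. With 1 frail library left, that library is assumed to vary like the controls.

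With the replicate number as a block, the counts were 285, 0, 108, 1, 262, 48 and 18 genes in the same order, 10 for the difference of effects and 1 class, the myonuclei-like one. Same-numbered libraries had correlations of deviations of −0.03 and 0.16 in all cells. The deviations of the 2 frail libraries mirror each other. Each correlation of frail 2 is therefore that of frail 1 with its sign turned (0.16 and −0.16 against control 2). The correlations thus cannot decide whether same-numbered animals are pairs, and no label ties them.

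Of 1417 values under alternatives, for 81 pairs of a named gene and a set of cells, 1079 kept direction and side of the threshold, 155 no longer passed, 156 newly passed and 27 turned sign, in 14 genes. In all cells Ret was 0.38 without frail 2 and 0.0482 without control 3, Cdkn1a 0.00153 and Cdkn2a 0.02 without frail 2, and Cdkn2a 0.27 without control 2. Col1a1 was 0.53 with the block, 0.0488 at 5% mitochondrial UMIs, 0.11 without frail 2 and 0.52 without control 3. Col3a1 was −0.00769 with upper-quartile factors, −0.0208 with doublets kept, −0.0458 with all barcodes, −0.0152 at 20% mitochondrial UMIs, −0.0709 without the keratin-led cluster, and −0.12, −0.02 and −0.28 without frail 1, control 1 and control 2. In myonuclei-like cells Adamts5 was 0.45 with doublets kept. Over the fits with 1 replicate left out, log2 changes ranged in all cells from −1.62 to 0.38 for Ret, −0.46 to 0.00153 for Cdkn1a, −1.57 to 0.27 for Cdkn2a, −0.42 to 0.52 for Col1a1 and −0.28 to 0.41 for Col3a1. They ranged in myonuclei-like cells from −0.0453 to 1.35 for Trim63 and −0.18 to 1.40 for Fbxo32, each lowest without frail 2, and from 1.52 to 2.57 for Isg15 with frail 2 kept. Without frail 2 the fit gave −7.22 for Isg15, which is counted among the turned signs but rests on 0 UMIs in a sum of 17491 and is no measured fold. In endothelial-like cells they ranged from −0.41 (without frail 2) to 0.76 for Aldh1l1, and from −0.85 to 1.99 for Gbp4 and −1.11 to 2.23 for Cd74, lowest without frail 1. Gdf15 in mural-like cells ranged from −0.29 (without frail 1) to 0.40, and Pax7 in satellite-like cells was −0.03 without control 1 and −0.24 without control 2.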

Other observations

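An arterial endothelial cluster, led by Cytl1, Sema3g, Gja5 and Gkn3, made up 4.02% and 3.45% of frail libraries and 1.85%, 1.40% and 1.36% of control libraries. Within endothelial-like cells it made up 13.2% and 7.97% against 5.51%, 4.98% and 7.95%, so that frail 2 and control 3 were nearly equal. Gkn3 stood at 38.0 and 26.7 plain CPM over frail endothelial-like cells and at 8.47, 7.65 and 16.02 over control ones. The share of this cluster was singled out after its values were seen and was not tested.

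The capillary-like endothelial clusters differed more between the 2 frail libraries than between groups. A cluster led by Aqp1, Iigp1, Timp4 and Slc1a1 held 51.4% of the endothelial-like cells of frail 1 and 5.87% of those of frail 2, with 28.7%, 43.3% and 39.2% in controls. A cluster led by Aqp1, Cd300lg and Gpihbp1 held 13.6% and 57.5%, with 37.3%, 33.7% and 33.4% in controls. In endothelial-like cells as a whole, the guanylate-binding protein Gbp4 stood at 583 and 81.3 CPM against 145, 188 and 106, and Cd74 at 620 and 61.2 against 115, 166 and 116. Their log2 changes of 1.18 and 1.36 were −0.85 and −1.11 without frail 1, so frail 1 sets their direction.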
